A study of Drosophila mettleri with 18 samples.

How the data were processed

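RNA sequencing measured transcript levels in larvae of the fly Drosophila mettleri. Larvae from the Santa Catalina Island population and from the Sonoran population were reared on lab food (an instant Drosophila medium), on coastal prickly pear cactus or on saguaro cactus. Each population was represented by 3 strains, and each strain was reared on all 3 foods, which gave 18 libraries in 6 groups of 3. Per the labels' protocols, each library came from a pool of 10 larvae aged 8 days, RNA was extracted with Tri-reagent, and every library was divided between both lanes of an Illumina HiSeq, so lane and group were not confounded. Replicates 1, 2 and 3 in the text are strains C-M, C-7 and C-9 for Santa Catalina and strains T-22, T-27 and T-28 for Sonoran.

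The values the authors deposited are whole-number counts per assembled gene: totals differed between libraries and every entry was whole. Whole entries do not show whether the counts had been rounded. Per the series' design text, reads were assembled de novo with Trinity and the sequences of each assembled gene were merged into 1 count per gene. The program that counted the reads, its version and any rounding or filter on genes are not given in the sources used here. Per the submitters' processing notes, edgeR was used, with no version given. The table holds 15947 features, 3 of them at 0 in every library, in 12153 assembly components, of which 9933 hold 1 feature. A feature name gives its component and its number within that component. The files do not pair feature names with gene names, so features are called by their assembly names, at most 2 that rose and 2 that fell per comparison, and no gene function is stated. The gene lists that had been set down in case gene symbols were given could not be used. Features of 1 component can be near-identical copies or versions of a gene, and reads could be divided between them, so their separate levels are uncertain.

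Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features with too few counts were removed with filterByExpr on the 6 groups, which left 12514, and library sizes were scaled with TMM factors. A single model of 6 group means was fitted to all 18 libraries (12 residual degrees of freedom) and each comparison was tested as a contrast with the quasi-likelihood F test. A feature was called when its Benjamini-Hochberg adjusted p was below 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Because the 3 libraries of a strain are not separate samples of its population, the comparison of populations over the 3 foods used the counts summed per strain, 3 strains against 3, with 13129 features tested. Differences between the populations in their food responses were tested as interaction contrasts. CPM values are scaled with the TMM factors, means are given with the SD over strains, and log2 CPM for principal components used a prior count of 2. These designs, the other settings to try and the rule for naming features were set before the data were examined. The rule takes, per comparison, the 2 called features with the largest fold change in each direction that had a mean of at least 5 CPM on the higher side and no overlap between the libraries of the sides. Other features named are said to have been chosen after their values were seen.

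The strain pairs the libraries of a population across foods, since the labels give the same strain on each food. Deviations from the group means had a median correlation of 0.112 between libraries of the same strain on different foods, from -0.325 to 0.617, and 12 of 18 such pairs were over 0.1. A fit with strain as a replicate block was therefore an alternative. Replicate numbers do not pair strains between the populations. No pair of libraries was a repeat of the other: within a group the smallest chi-square per degree of freedom between 2 libraries was 26.4.

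Depth ranged from 6769906 to 16115982 counts per library. Where every library of a side was at 0, a fold is given as a lower bound against a floor of 3 counts over that side. The floor and the exact 95% Clopper-Pearson intervals cover counting error only, because reads without molecular identifiers are not independent molecules. On data simulated from the real means, depths and dispersions, the fit recovered 52.0% of features changed by log2 1 and 84.8% of those changed by log2 2 for prickly pear against lab food over both populations (12155 features). It recovered 13.3% and 59.0% for that comparison in Sonoran alone (12165 features), 16.3% and 70.1% for the populations on lab food (12156 features), 35.0% and 81.0% for the populations over the 3 foods (12501 features), and 3.00% and 44.4% for the difference in response to prickly pear (12131 features). Each simulation changed 100 features by each size. Libraries were simulated independently, without a strain effect shared across foods, so the recovery over the 3 foods may be overstated.

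The other settings tried were RLE size factors, no filter on low counts, DESeq2 1.42.0, counts thinned to the smallest library, the replicate block, the 6 libraries of a comparison alone, each library or strain left out in turn, and, for the populations over the 3 foods, 18 libraries as separate samples and limma 3.58.1 voom with strain as a random block. Thresholds of 0.01 and 0.10 were tried for overlaps, minimums of 5 and 20 counts for features present on a single side, and prior counts of 0.5 and 5 for the principal components. Scaling by library totals alone, and leaving the Santa Catalina saguaro replicate 1 library out of every fit, were added after seeing the data.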

Results

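Transcript levels were measured in 18 pools of D. mettleri larvae from 2 populations. The series asks which transcript differences go with the use of different cactus hosts. Library totals averaged 14037200 ± 1008040 counts in Santa Catalina (SD, n = 9) and 12041800 ± 2763770 in Sonoran (SD, n = 9), and the smallest library was Sonoran saguaro replicate 2 with 6769906 counts. Food separated the libraries more than population did. The first principal component held 52.5% of the variance, with 54.3% of its spread lying between foods and 0.429% between populations. Between the 6 groups lay 73.5%, so part of the spread between groups belonged to neither food nor population alone. Lab food and saguaro libraries overlapped on this component. The fourth component, with 4.8% of the variance, had 63.7% of its spread between populations. The strains are separate fly stocks with a single pool on each food. The p-values therefore measure the spread between strains together with that between pools and libraries. For the populations on single foods, that spread was estimated from all 18 libraries as if each were independent. The libraries of a strain on the other foods are not separate samples of its population, so those p-values may be too small. The main fit did not pair the foods within strains.

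**Figure D1:**
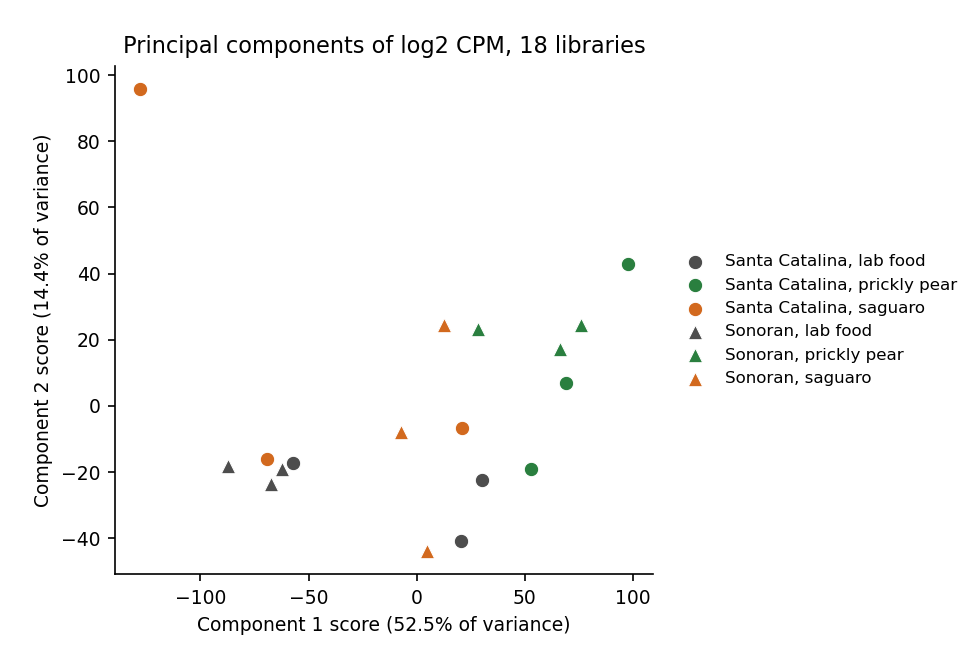
Scores of the 18 libraries on the first 2 principal components of log2 CPM (unitless scores; colour marks food, circles Santa Catalina and triangles Sonoran). The 6 prickly pear libraries lie between 28.4 and 97.9 on component 1, a range that also holds Santa Catalina lab food replicate 2 at 30.1. Santa Catalina saguaro replicate 1 stands apart at -128.1 on component 1 and 95.7 on component 2.

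Larvae on prickly pear differed widely from larvae on lab food. Over both populations, 2446 features rose on prickly pear and 2369 fell, together 38.5% of the 12514 tested (edgeR quasi-likelihood test, adjusted p below 0.05). Abundant transcripts fell and scarce ones rose: of 265 features averaging 500 CPM or more, 186 fell and 7 rose, while of 4907 features under 5 CPM, 1249 rose and 323 fell. The falling features held 61.2% ± 5.12 of all counts on lab food and 38.2% ± 4.93 on prickly pear, and the rising features 3.63% ± 1.10 and 9.79% ± 2.53 (SD, n = 6 each). The features that make up these shares were selected on the same libraries, so the shares describe the calls and are not separate evidence for them.

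comp39909_c2 had 0 counts in all 6 lab food libraries and 29 to 239 counts on prickly pear, where it averaged 6.31 ± 3.13 CPM (SD, n = 6). It was at least 162-fold higher on prickly pear (adjusted p = 0.00313, edgeR), against a floor of 3 counts over the 6 lab food libraries. comp32121_c0 rose from 3.85 ± 8.38 to 124 ± 66.5 CPM (SD, n = 6; log2 fold change 6.16, SE 1.41, adjusted p = 0.00587, edgeR). Santa Catalina lab food replicate 2, at 20.9 CPM, carries the lab food mean of comp32121_c0, the other 5 libraries lying at 0.151 to 0.904 CPM, and without that strain the log2 fold change was 8.36 (adjusted p = 0.00285, edgeR). In the other direction, comp19355_c0 had 4 to 231 counts in the lab food libraries and 0 in all 6 prickly pear libraries, at least 249-fold lower on prickly pear (adjusted p = 0.00515, edgeR). This feature was no higher on saguaro (log2 fold change 0 between the cacti). Its log2 fold change against lab food was -9.63 on saguaro and on prickly pear alike, so the fall was not particular to prickly pear. The difference between saguaro and lab food was not called, however (adjusted p = 0.11, edgeR). comp29237_c0 fell from 23.0 ± 18.6 to 0.0503 ± 0.0600 CPM (SD, n = 6; log2 fold change -8.54, SE 1.08, adjusted p = 0.000866, edgeR). comp39909_c2 was the only feature with 0 counts in every library of a food and at least 10 in every library of another, over all food pairs and the populations. No other split of the libraries of these foods, within each population, gave such a feature. Whether features absent on a food come from the larva or from its gut content was not tested.

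The direction of these changes is relative to the TMM scaling. With library totals alone, chosen after seeing the data, the median log2 fold change moved from 0.08 to 0.72 and the calls to 7601 higher and 946 lower. Leaving out Santa Catalina replicate 3, Sonoran replicate 1 or Sonoran replicate 3, each a strain, gave 2490, 2039 and 1891 calls.

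**Figure D2:**
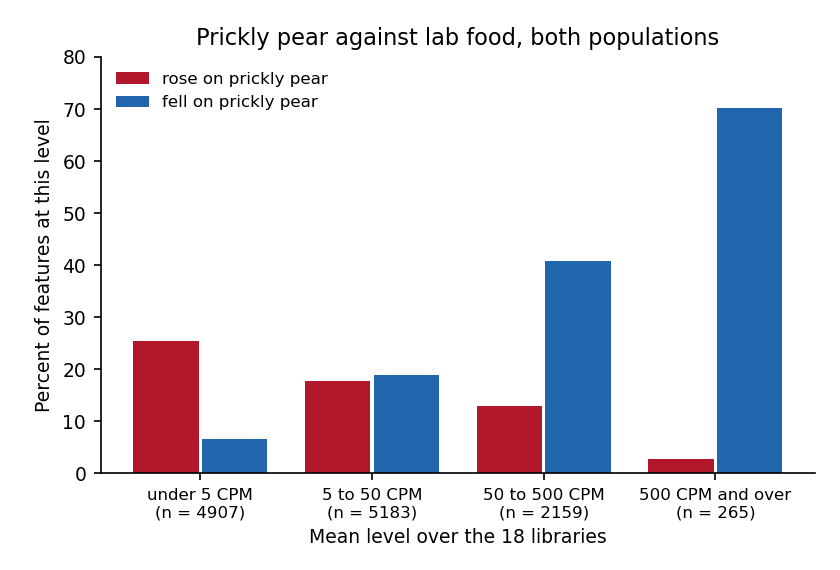
Percent of features that rose (red) or fell (blue) on prickly pear against lab food over both populations, by mean level over the 18 libraries in CPM, with the number of features at each level. Under 5 CPM 25.5% rose and 6.58% fell, and at 500 CPM and over 2.64% rose and 70.2% fell (with library totals alone, 61.4% of the scarcest rose and 28.7% of the most abundant fell).

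In Sonoran larvae alone, 1821 features rose and 1797 fell on prickly pear against lab food. comp29514_c0 rose from 0.141 ± 0.0461 to 259 ± 93.8 CPM (SD, n = 3; log2 fold change 10.75, SE 3.42, adjusted p = 0.0327, edgeR) and comp39909_c2 from 0 counts to 6.37 ± 1.54 CPM, at least 75.2-fold (adjusted p = 0.0182, edgeR). comp19355_c0 was at least 125-fold lower (adjusted p = 0.0225, edgeR) and comp29237_c0 fell with a log2 fold change of -9.14 (SE 1.56, adjusted p = 0.00736, edgeR). In 14 other settings comp29514_c0 lost its call in 5 (largest adjusted p 0.108) and comp39909_c2 in 3, and comp19355_c0 lost it in 2 of 13. In Santa Catalina larvae, 1 feature rose and 52 fell. comp29237_c0 fell there from 16.2 ± 11.7 to 0.0631 ± 0.0655 CPM and comp35025_c0 from 696 ± 456 to 5.51 ± 1.26 CPM (SD, n = 3), each with an adjusted p of 0.0385 (edgeR). Their calls were lost in 7 and 8 of 14 other settings. With strain as a replicate block, 19 features were called in Santa Catalina and 3263 in Sonoran.

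The unequal counts of calls are no test of unequal responses. The difference in response to prickly pear was not called for any feature (edgeR), with 555 features at an unadjusted p under 0.05 against 625.7 by chance and 0 calls by DESeq2. The populations' log2 fold changes had r = 0.811 across features, which are not independent replicates, with a covariance of 0.972. The slope of the Santa Catalina fold changes on those of Sonoran was 0.469, a value that strain noise lowers, and a difference in size was not tested. On simulated data the test of the difference in response recovered 3.00% of log2 1 changes, so the lack of calls does not show that the responses were alike. The sign was the same for 82.6% of all features and for 53 of the 53 called in Santa Catalina. With the foods exchanged within strains, 1 of 16 combinations over both populations, the real one, gave as large a correlation of log2 CPM differences as the real 0.879 (exact permutation p = 0.0625, two-sided, the smallest this design can give). Both populations called 50 features in the same direction: 1 that rose (0.146 by the product of the list sizes) and 49 that fell (7.47). That product takes the lists as independent, but 1 fit with a shared estimate of spread gave both lists. In Sonoran, library totals alone gave 6699 higher and 781 lower; leaving out lab food replicate 1, 2 or 3 gave 1966, 2145 and 860 calls, and prickly pear replicate 1 or 3 gave 987 and 664. In Santa Catalina, DESeq2 gave 686 calls (201 higher, 485 lower), RLE size factors left 4, library totals alone 1, and the 6 libraries alone 0; without lab food replicate 1 or prickly pear replicate 1 or 3 there were 0, without lab food replicate 3 there were 3, and without prickly pear replicate 2 there were 457.

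On saguaro, 20 features rose and 25 fell against lab food over both populations. The largest rise was that of comp36625_c0, from 41 ± 10.9 CPM on lab food to 1604 ± 354 CPM on saguaro (SD, n = 6; log2 fold change 5.29, SE 0.63, adjusted p = 0.00166, edgeR), and it was also higher on prickly pear than on lab food (log2 fold change 3.48, SE 0.58, adjusted p = 0.00161, edgeR). comp34213_c0 rose from 27.9 ± 14.8 to 227 ± 98.4 CPM (SD, n = 6; adjusted p = 0.000537, edgeR). comp33240_c0 fell from 34.5 ± 22 to 2.01 ± 1.10 CPM (adjusted p = 0.00214, edgeR) and comp36764_c0 from 95.1 ± 61.9 to 6.28 ± 5.0 CPM (adjusted p = 0.0108, edgeR), with SD over 6 libraries in each. The count fell to 5, 16, 4, 11 and 23 without Santa Catalina replicate 1 or 2 or Sonoran replicate 1, 2 or 3, and DESeq2 called 209. The number of calls does not measure the size of the response. In 13 other settings comp36764_c0 lost its call in 3 and comp36625_c0 in 2.

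Within populations, 5 features rose and 2 fell on saguaro in Santa Catalina, and 3 rose in Sonoran. All 3 of the Sonoran calls were also called in Santa Catalina (0.00120 by the product of the list sizes, which takes lists and features as independent). comp34213_c0 and comp34213_c1, features of 1 component, rose in both: in Santa Catalina to 286 ± 115 and 79.6 ± 35.0 CPM on saguaro from 37.3 ± 14.9 and 11.3 ± 4.68 on lab food, and in Sonoran to 167 ± 19.3 and 45.1 ± 7.37 CPM from 18.5 ± 7.79 and 4.97 ± 1.90 (SD, n = 3). Their adjusted p-values were 0.0389 in Santa Catalina and 0.0218 in Sonoran (edgeR), and their calls were lost in 8 of 13 and 6 of 14 other settings. comp37436_c0 fell in Santa Catalina from 269 ± 119 to 34.2 ± 12.8 CPM and comp39042_c0 from 122 ± 11 to 55.4 ± 2.55 CPM (SD, n = 3, adjusted p = 0.0389 for each, edgeR), calls lost in 7 and 8 of 13. With strain as a replicate block, 1 feature was called in Santa Catalina, which was not among the 7, and 7 in Sonoran, 1 of them shared. DESeq2 gave 60 calls in Santa Catalina and 273 in Sonoran. In Santa Catalina, RLE size factors or the 6 libraries alone left 0 calls; so did leaving out lab food replicate 1 or 3 or saguaro replicate 1 or 3, while without lab food replicate 2 there was 1 and without saguaro replicate 2 there were 290. In Sonoran, the 6 libraries alone gave 657 calls, library totals alone 9 and thinned counts 14; without lab food replicate 1, 2 or 3 or saguaro replicate 3 there were 0, without saguaro replicate 1 there was 1, without saguaro replicate 2 there were 8, and without Santa Catalina saguaro replicate 1 there were 18.

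**Figure D3:**
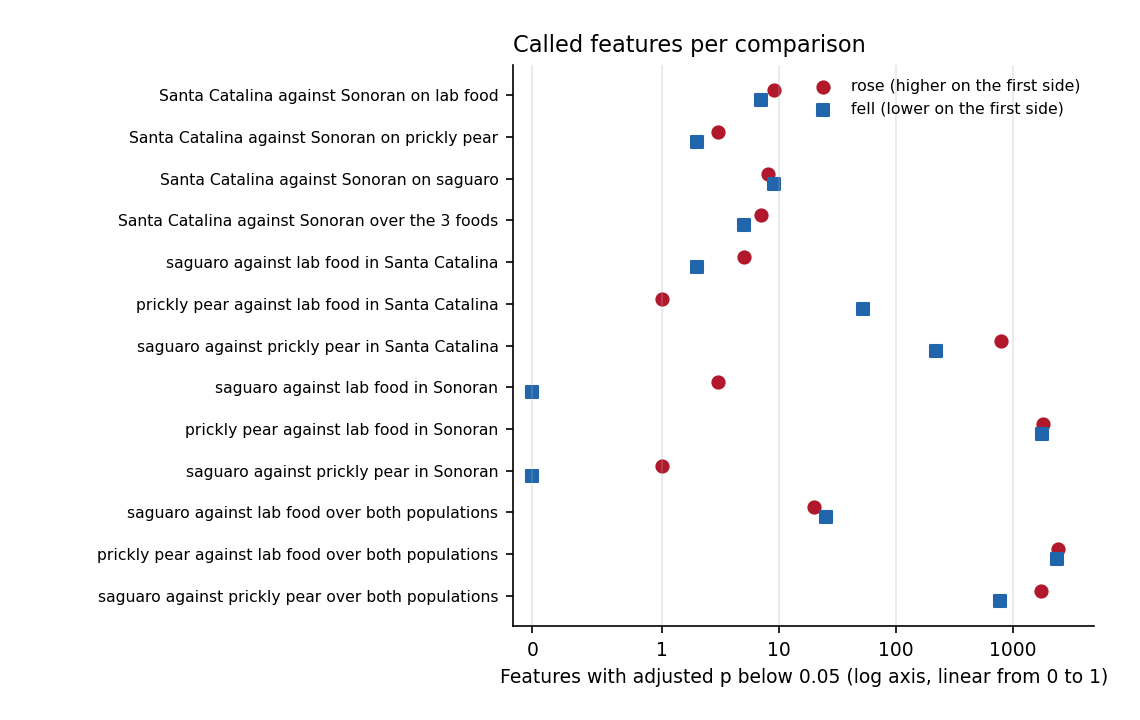
Number of features called higher (red circles) and lower (blue squares) on the first-named side of each comparison, adjusted p below 0.05, on a log axis that is linear from 0 to 1. Prickly pear against lab food over both populations gave 2446 and 2369, and no comparison of populations gave more than 9 in either direction.

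The difference between the populations in their response to saguaro was not called for any feature by edgeR, with or without the replicate block. It had 2300 features at an unadjusted p under 0.05 against 625.7 by chance, and DESeq2 called 377. Leaving out Santa Catalina replicate 2 gave 741 calls, 711 of them lower in Santa Catalina. Across features the populations' saguaro responses had r = -0.268 (covariance -0.192), with the same sign for 42.5%. Of 16 combinations with the foods exchanged within strains, 9 gave a correlation of log2 CPM differences as large as the real -0.368 in either direction (exact permutation p = 0.562, two-sided). Leaving out Santa Catalina saguaro replicate 3 moved r to -0.0315 and leaving out saguaro replicate 2 moved it to -0.518. The joint test of any difference in food response called 0 features with edgeR, 1197 of them at an unadjusted p under 0.05, and 59 with DESeq2.

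Saguaro and prickly pear also differed from each other. Over both populations, 1740 features were higher on saguaro and 781 lower. Of the 265 features at 500 CPM or more, 108 were higher on saguaro and 0 lower, while under 5 CPM 155 were higher and 347 lower. comp21967_c0 was higher on saguaro, at 12.1 ± 14.0 against 0.371 ± 0.338 CPM (adjusted p = 0.0116, edgeR), as was comp32557_c0, at 10.3 ± 12.3 against 0.629 ± 0.571 CPM (adjusted p = 0.0202, edgeR), which lost its call in 4 of 13 other settings. comp21967_c0, comp33304_c0 and comp34454_c2 each lost theirs in 2 of 13. The Santa Catalina saguaro replicate 3 library held the most of comp32557_c0 and comp21967_c0, at 35.0 and 39.0 CPM, with the other 5 saguaro libraries at 1.87 to 8.01 and 1.83 to 12.5 CPM. Without that strain the log2 fold changes went from 3.94 to 2.52 for comp32557_c0, from 5.03 to 3.75 for comp21967_c0, from -4.92 to -3.59 for comp33304_c0 and from -4.49 to -3.50 for comp34454_c2. comp33304_c0 was lower on saguaro, at 1.99 ± 0.914 against 61.8 ± 64.7 CPM, as was comp34454_c2, at 0.216 ± 0.219 against 5.46 ± 5.30 CPM (SD, n = 6, adjusted p = 0.00806 for each, edgeR). Library totals alone turned the direction of the calls, with 711 higher and 7286 lower on saguaro (median log2 fold change -0.68 against -0.07), and DESeq2 gave 2071 higher and 1744 lower. The calls fell to 1624 without the Santa Catalina saguaro replicate 1 library, to 0 without Santa Catalina replicate 1 or Sonoran replicate 1, and to 1055, 1066 and 1111 without Santa Catalina replicate 3 or Sonoran replicate 2 or 3; without Santa Catalina replicate 2 there were 4884.

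In Santa Catalina, 798 features were higher and 219 lower on saguaro than on prickly pear. comp31297_c0 was at 78.8 ± 57.2 against 0.554 ± 0.516 CPM (adjusted p = 0.0435, edgeR) and comp29237_c0 at 8.30 ± 10.4 against 0.0631 ± 0.0655 CPM (SD, n = 3, adjusted p = 0.0374, edgeR). comp39909_c2 was at 0 counts on saguaro, at least 70.7-fold lower than on prickly pear (adjusted p = 0.0443, edgeR), and comp33304_c0 at 1.99 ± 1.14 against 55.8 ± 80.1 CPM (SD, n = 3, log2 fold change -4.78, adjusted p = 0.0450, edgeR). Prickly pear replicate 3 carries that mean of comp33304_c0, at 148 CPM against 15.5 and 3.86, and without it the log2 fold change was -2.25 (adjusted p = 0.206, edgeR). Saguaro replicate 3 likewise carries the mean of comp29237_c0, at 20.2 CPM against 3.75 and 0.933, and without it the log2 fold change went from 6.98 to 5.12 (adjusted p = 0.127, edgeR). In 13 other settings comp29237_c0 lost its call in 7, and comp31297_c0, comp39909_c2 and comp33304_c0 in 8. In Sonoran, comp39297_c4 alone was called, at 2194 ± 690 CPM on saguaro and 508 ± 183 on prickly pear (SD, n = 3, adjusted p = 0.0411, edgeR), a call lost in 8 of 14 other settings. Both counts became 0 with strain as a replicate block, and the Santa Catalina count was 0 with RLE size factors, with the 6 libraries alone, and without saguaro replicate 1 or 3 or prickly pear replicate 1 or 3; it was 428 with no filter, 6318 (370 higher, 5948 lower) with library totals alone, 3021 with DESeq2 (1555 higher, 1466 lower), 1568 without prickly pear replicate 2 and 4276 without saguaro replicate 2. The Sonoran count was 262 with DESeq2 and 26 with the 6 libraries alone, 0 without prickly pear replicate 1 or 3, saguaro replicate 1 or 2 or the Santa Catalina saguaro replicate 1 library, and 2 without prickly pear replicate 2. The difference between the populations was not called for any feature by edgeR or DESeq2 (248 at an unadjusted p under 0.05), and the responses had r = 0.734 across features and a covariance of 0.587, while the correlation of log2 CPM differences was 0.700, with 2 of 16 within-strain combinations as large (exact permutation p = 0.125, two-sided).

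Over both populations, 38 of the 45 features called on saguaro against lab food were called in the same direction on prickly pear against lab food, 16 that rose (3.91 by the product of the list sizes) and 22 that fell (4.73), and 0 in the opposite direction. These comparisons share all their lab food libraries, and the product of the list sizes takes the lists as independent, so part of the overlap may come from those libraries. Unchanged groups simulated against them 20 times shared 0 calls, which says nothing of this overlap because unchanged groups give next to no calls. They gave a mean r of 0.495 and a mean covariance of 0.0642, beside the observed r of 0.635 and covariance of 0.366, a difference in covariance of 0.302. With the lab food libraries divided between the comparisons in 18 ways, r averaged 0.403, from -0.0855 to 0.604, and the covariance averaged 0.243, against 0.603 and 0.313 with the libraries shared in the same fit. In Sonoran r was 0.881 and the covariance 1.27 (simulated 0.499 and 0.132), and all 3 saguaro calls were shared. In Santa Catalina r was 0.00680 and the covariance 0.00406 (simulated 0.498 and 0.127), and 2 of the 7 were shared.

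Between the populations, 7 features were called higher and 5 lower in Santa Catalina over the 3 foods, of 1566 at an unadjusted p under 0.05 (656.5 by chance). On simulated data without a shared strain effect this test recovered 35.0% of log2 1 differences, which may overstate its power, so smaller differences go largely uncalled. comp37185_c1 was at 716 ± 100.9 CPM in Santa Catalina and 6.65 ± 2.10 CPM in Sonoran (SD, n = 3 strains; log2 fold change 6.74, SE 0.27, adjusted p = 0.000561, edgeR). comp34913_c0 was at 0.473 ± 0.249 against 28.5 ± 5.0 CPM (log2 fold change -6.02, SE 0.33, adjusted p = 0.00162, edgeR; n = 3 strains). On prickly pear, though, the Sonoran libraries held 0.479 to 3.08 CPM of comp34913_c0 and the populations' difference was not called (adjusted p = 0.183, edgeR), and in Sonoran it fell on prickly pear against lab food (log2 fold change -5.38, SE 0.62, adjusted p = 0.00232, edgeR). Features comp37831_c13 and comp37831_c5 share a component and went opposite ways: comp37831_c13 was at 47.2 ± 16.7 against 1.28 ± 0.133 CPM and comp37831_c5 at 0.126 ± 0.172 against 39.9 ± 6.50 CPM (SD, n = 3 strains, adjusted p = 0.00337 for each, edgeR). DESeq2 called 245 features, the 18 libraries as separate samples 83 and limma voom with a random strain block 60 (28 higher, 32 lower); without Santa Catalina replicate 1 or 3, or Sonoran replicate 1, there were 7.

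On single foods, 16 features differed between the populations on lab food (9 higher and 7 lower in Santa Catalina), 5 on prickly pear (3 and 2) and 17 on saguaro (8 and 9), of 2199, 395 and 745 at an unadjusted p under 0.05 (625.7 by chance). Together with the 12 called over the foods these were 26 features. Of the 26, 4 were called on every food, 0 were called in opposite directions, and 23 had the same sign on all 3 foods. comp37185_c1 was at 844 ± 176, 564 ± 28.7 and 740 ± 156 CPM in Santa Catalina on lab food, prickly pear and saguaro, and at 9.70 ± 3.11, 5.09 ± 1.29 and 5.17 ± 2.40 CPM in Sonoran (SD, n = 3). comp37831_c5 had 0 counts in the Santa Catalina libraries on lab food and on prickly pear, at least 521-fold and 635-fold lower than in Sonoran (adjusted p = 0.000406 and 0.000517, edgeR). comp37687_c1 was lower in Santa Catalina on every food. On prickly pear it was at 5.38 ± 0.631 against 43.5 ± 0.723 CPM (SD, n = 3, adjusted p = 4.87e-07, edgeR). Its log2 fold change was -3.30 on lab food and -2.82 on saguaro (adjusted p = 2.24e-07 and 7.91e-07, edgeR). Over the 3 foods, with counts summed per strain, the adjusted p of comp37687_c1 was 0.000762 (edgeR). The single-food p-values take the libraries of a strain as independent and may be too small. On saguaro comp27976_c0 was higher in Santa Catalina, at 24.3 ± 17 against 0.355 ± 0.199 CPM (SD, n = 3, adjusted p = 0.0298, edgeR). That call was lost in 7 of 13 other settings (largest adjusted p 0.262). comp27976_c0 was also called over the 3 foods (log2 fold change 4.53, adjusted p = 0.0371, edgeR). It was not called on lab food or prickly pear (adjusted p = 0.189 and 0.231, edgeR).

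DESeq2 called 573, 33 and 58 features for the populations on lab food, prickly pear and saguaro, and the 6 libraries alone 6, 3 and 3. In the fits of the 6 libraries alone, no strain was counted more than once. Those fits also have less power, so their lower counts do not show how much repeated strains matter. On lab food the count was 5, 534, 7, 8 and 5 without Santa Catalina lab food replicate 2 or 3 or Sonoran lab food replicate 1, 2 or 3, and 29 without Santa Catalina saguaro replicate 1; on prickly pear it was 11 without Santa Catalina prickly pear replicate 3; on saguaro it was 6, 28, 6, 6, 10 and 7 without Santa Catalina saguaro replicate 1, 2 or 3 or Sonoran saguaro replicate 1, 2 or 3.

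**Figure D4:**
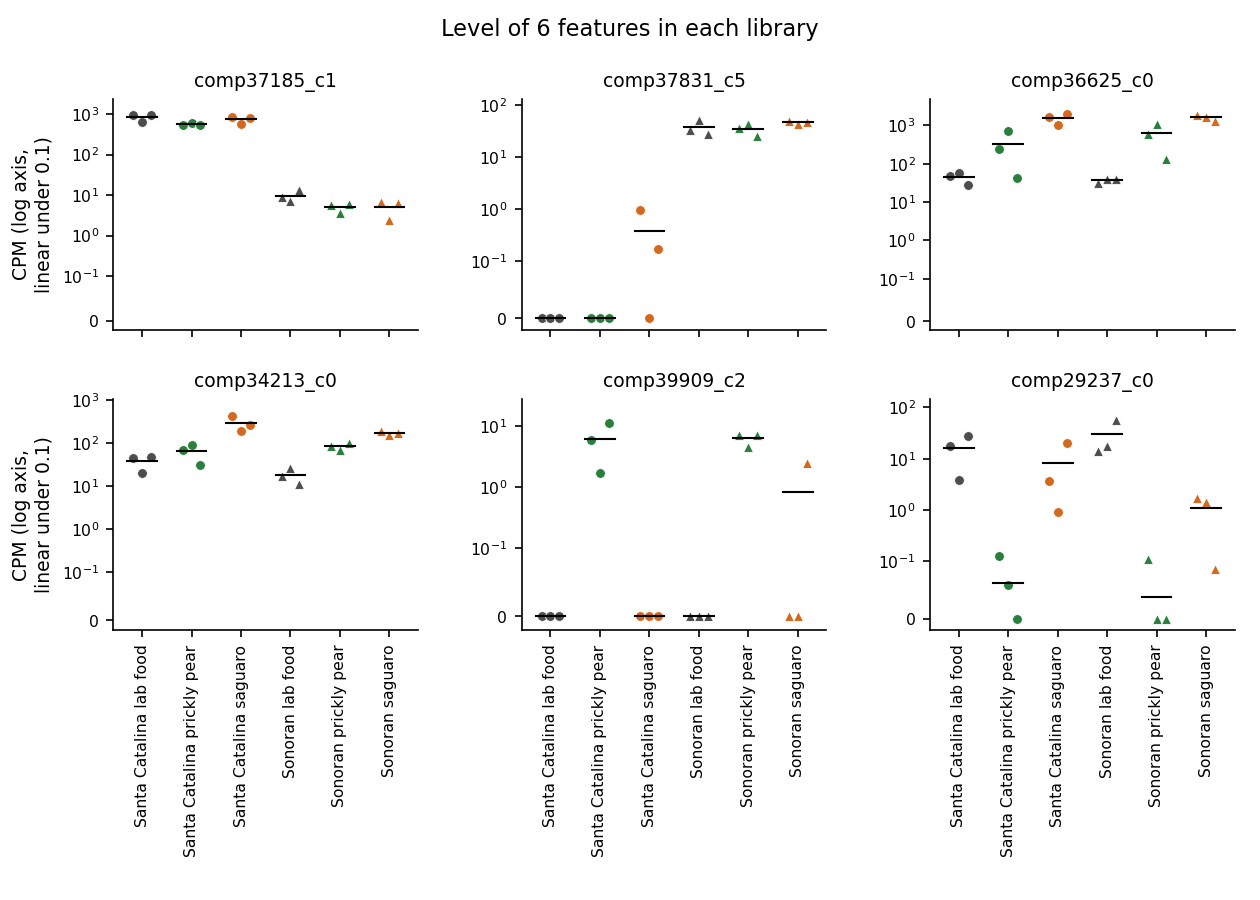
Level in CPM of 6 features named in the text in each library, on a log axis that is linear under 0.1 (circles Santa Catalina, triangles Sonoran, black lines group means of n = 3). comp37185_c1 and comp37831_c5 part the populations on every food, comp36625_c0 and comp34213_c0 are highest on saguaro, and comp39909_c2 is at 0 in all 6 lab food libraries.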

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

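In this part, the test of depth between the foods was set before its result was seen, and all the other tests were chosen after the results they bear on. In 49 groups of 6 or 9 libraries, 5 held a library far from the rest by the gap between the end value and its neighbour, where chance gives about 1 in 20. Between the populations, 18 measures of the libraries by food pair were compared.

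Santa Catalina saguaro replicate 1 had 25.5% of its features at 0, against 12.8% for the next of the 6 saguaro libraries and 12% for the next of the 9 Santa Catalina libraries. It alone lacked 1195 features that the other 17 libraries all held, against at most 59 for any other library. Lower depth is argued against, since after thinning to the smallest total 29.9% of its features were at 0 and at most 19.1% in any other library. A loss of molecules before sequencing would strike features of 1 level alike, yet of the 756 steadiest features at 2 to 8 CPM it lacked 0.661% (exact 95% interval 0.215% to 1.54%), against 13.1% of all features at that level. A candidate explanation is that it sits at the low end of the features that rise on prickly pear: 51.5% of its missing features at 2 to 8 CPM rose on prickly pear in the separate Sonoran libraries, against 12.7% of those it held, and whether larval state, strain or handling put it there was not tested.

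Over both populations, more abundant features were called lower on prickly pear and more scarce ones higher. By population the median log2 fold change of features at 500 CPM or more was -0.60 in Santa Catalina and -0.73 in Sonoran, and that of features under 5 CPM 0.28 and 0.53, untested medians, with 1 feature of any level called higher in Santa Catalina. With the 10 most abundant features removed before scaling, 72.2% of features at 500 CPM or more fell, against 70.2% with them. TMM scaling already trims the most abundant features, so this value could hardly move and cannot decide on scaling. With every library thinned to 6769906 counts 70.2% fell. Features this abundant keep many counts after thinning, so this value could hardly move and cannot decide on depth. No thinned value is given for the scarce features. With library totals alone 28.7% fell, so the choice of scaling stays open beside a response to the food or a difference in growth stage, which may underlie it and were not tested.

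Of the features called between the populations, versions of 1 gene assembled apart could explain comp37831_c5 and comp37831_c13, whose summed level was 47.3 ± 16.9 CPM in Santa Catalina and 41.2 ± 6.57 CPM in Sonoran (SD, n = 3 strains), a log2 ratio of 0.20. For most of the 15 called features with another tested feature in their component this is argued against, since 3 of them had an opposite one over log2 1. The other called features have none, and versions assembled in another component would be missed. Over the 1310 components with exactly 2 tested features, the populations' differences of both features had a Spearman rho of 0.547 across components. A difference in expression between the populations also stays open, and was not tested apart from sequence differences that alter how reads are assigned.

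The saguaro response went opposite ways in the populations in 3 measures: every Santa Catalina strain moved one way against lab food and every Sonoran strain the other. Santa Catalina minus Sonoran was -132.5 for the component 1 score (means -56.8 ± 79.7 and 75.8 ± 21.2, SD, n = 3 strains), 4.96 percentage points for the share of counts in the 1000 most abundant features (2.46 ± 2.66 and -2.50 ± 1.97) and -0.320 for the TMM factor (-0.151 ± 0.150 and 0.169 ± 0.136). Each had an exact permutation p of 0.1, two-sided, the smallest that 3 strains against 3 can give, so these differences did not pass a test. The 3 measures are not separate observations. Over all 18 libraries, Santa Catalina saguaro replicate 1 and Santa Catalina prickly pear replicate 3 held the end values of each.

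comp33240_c0 on saguaro reached 2.37 on the log2(CPM + 1) scale in Santa Catalina saguaro replicate 1, with the next library at 1.53. comp32121_c0 on lab food reached 4.46 in Santa Catalina lab food replicate 2, with the next at 0.929. comp21967_c0 on prickly pear reached 1.04 in Santa Catalina prickly pear replicate 2, with the next at 0.379.

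Each strain was reared on every food, so the splits that keep this pairing exchange the foods within strains, and all 32 of them were fitted for each food pair over both populations. For prickly pear against lab food 1 of 32 (the real one) gave as many calls, 4815 with 3582 the highest of the others. For saguaro against prickly pear 1 of 32 did, 2521 with 1446. In both the highest other split exchanged the foods of strain C-7 (Santa Catalina replicate 2) alone. For saguaro against lab food 1 of 32 did, 45 with 0. Each share was 0.03125, the smallest that 32 splits can give. It argues against chance for each food pair taken alone, is not adjusted over the pairs, and does not exclude chance. Of 40 splits drawn within the populations without regard to strain, 1 gave as many calls for prickly pear against lab food (highest other 1), 1 for saguaro against prickly pear (highest other 0), and 2 for saguaro against lab food (highest other 1156). The real count for saguaro against lab food was thus the highest with strains kept paired and not without. The split that gave 1156, and a split of the Santa Catalina saguaro and lab food libraries that gave 2240 against a real 7, put Santa Catalina saguaro replicates 1 and 3 with lab food replicate 3 against saguaro replicate 2 with lab food replicates 1 and 2, which points to a structure of these libraries other than food.

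The remaining comparisons have 10 splits, too few for a share under 0.05. The real count and the highest other were 16 and 0 for the populations on lab food, 5 and 0 on prickly pear, 17 and 0 on saguaro and 12 and 1 over the foods, with 1 split as large in each. They were 53 and 0 for prickly pear against lab food and 1017 and 0 for saguaro against prickly pear in Santa Catalina, and 3 and 0, 3618 and 0, and 1 and 0 for saguaro against lab food, prickly pear against lab food and saguaro against prickly pear in Sonoran. For saguaro against lab food in Santa Catalina 2 of the 10 were as large. For the 4 tests of population differences in response all 10 splits gave 0 calls, as the real one did.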

How the results depend on the processing

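In this part, the fits with library totals alone and the fits of every comparison without Santa Catalina saguaro replicate 1 were chosen only after the data were seen, and every setting chosen earlier was run. No named feature changed direction: of 605 pairs of a named feature and an alternative, 473 kept direction and an adjusted p under 0.05, and 132 kept direction alone. The named features had been picked for large differences without overlap between the sides. Their direction could therefore hardly change, and this says little of other features. Of the 45 named features with their comparison, 19 kept both in every alternative. The number of calls varied widely between the settings, and the cause was not tested. Fewer libraries give less power, which does not account for the counts that rose when a library was left out. The smallest library, with 6769906 counts, limits what is seen of scarce features, and thinning every library to that total moved the calls to 14 for saguaro against lab food in Sonoran and to 3 for saguaro against prickly pear in Sonoran, and no other count by over 1.5 times.

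DESeq2 gave 573 calls for the populations on lab food, 33 on prickly pear, 58 on saguaro and 245 over the foods. In Santa Catalina it gave 60 for saguaro against lab food, 686 for prickly pear against lab food (201 higher, 485 lower) and 3021 for saguaro against prickly pear. In Sonoran it gave 273 for saguaro against lab food and 262 for saguaro against prickly pear. Over both populations it gave 209 for saguaro against lab food and 3815 for saguaro against prickly pear, and for the population differences 377 in the response to saguaro against lab food (50 higher, 327 lower in Santa Catalina) and 59 in the joint test.

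The 6 libraries of a comparison alone gave 6, 3 and 3 calls for the populations on lab food, prickly pear and saguaro, and 0 for each of the 3 food pairs in Santa Catalina. In Sonoran they gave 657 for saguaro against lab food and 26 for saguaro against prickly pear. Over the foods, the 18 libraries as separate samples gave 83 and limma voom 60, with a consensus correlation of 0.0487 between the libraries of a strain.

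RLE size factors gave 0 calls for saguaro against lab food, 4 for prickly pear against lab food and 0 for saguaro against prickly pear in Santa Catalina, and 2 for saguaro against prickly pear in Sonoran. With no filter, saguaro against prickly pear gave 428 in Santa Catalina and 2 in Sonoran. Library totals alone gave 1 for prickly pear against lab food and 6318 for saguaro against prickly pear in Santa Catalina. In Sonoran they gave 9 for saguaro against lab food, 7480 for prickly pear against lab food and 0 for saguaro against prickly pear. Over both populations they gave 8547 for prickly pear against lab food and 7997 for saguaro against prickly pear. The replicate block gave 1, 19 and 0 for saguaro against lab food, prickly pear against lab food and saguaro against prickly pear in Santa Catalina, and 7 and 0 for saguaro against lab food and saguaro against prickly pear in Sonoran. It moved no other count for a food comparison or a difference in response by over 1.5 times. For the populations on single foods, the block joined strains by replicate number. Those numbers do not pair strains between the populations, so these fits do not bear on strain.

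With 1 library left out, the calls ranged from 5 to 534 for the populations on lab food, 4 to 11 on prickly pear and 6 to 28 on saguaro. In Santa Catalina they ranged from 0 to 290 for saguaro against lab food, 0 to 457 for prickly pear against lab food and 0 to 4276 for saguaro against prickly pear. In Sonoran they ranged from 0 to 18 for saguaro against lab food, 664 to 4686 for prickly pear against lab food and 0 to 2 for saguaro against prickly pear. With 1 strain or library left out, they ranged from 7 to 13 for the populations over the foods, and over both populations from 4 to 42 for saguaro against lab food, 1891 to 5758 for prickly pear against lab food and 0 to 4884 for saguaro against prickly pear. The population difference in the response to saguaro against lab food ranged from 0 to 741.

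At adjusted p thresholds of 0.01 and 0.10, the calls shared by the populations were 0 and 5 for saguaro against lab food and 0 and 212 for prickly pear against lab food, and 2 at 0.10 for saguaro against prickly pear. The calls shared by the cacti against lab food were 0 and 4 in Santa Catalina, 0 and 19 in Sonoran, and 6 and 59 over both populations. With a minimum of 5 counts, 2 features were present on a single side, comp39909_c2 and comp101259_c0, the latter chosen after its values were seen.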

Other observations

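In this part, both features were chosen only after their values were seen, and no explanation was tested. comp37474_c2 held 12.4% ± 1.58 of all counts on lab food, 4.60% ± 1.29 on prickly pear and 12.4% ± 3.23 on saguaro (SD, n = 6 each). It was lower on prickly pear than on lab food (log2 fold change -2.04, SE 0.38, adjusted p = 0.00241, edgeR). comp39192_c0 held 0.726% ± 1.5 on lab food, 7.39% ± 2.61 on prickly pear and 1.86% ± 2.39 on saguaro (SD, n = 6 each), and its difference between prickly pear and lab food did not pass the test (log2 fold change 3.67, SE 1.45, adjusted p = 0.0565, edgeR). Santa Catalina lab food replicate 2 carries that lab food mean, at 3.78%, with the other lab food libraries at 0.00866% to 0.306%. The saguaro libraries ranged from 0.00209% to 6.19%, the highest being Sonoran saguaro replicate 3.

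The 1000 most abundant features held 80.6% ± 1.99 of counts on lab food, 73.7% ± 2.36 on prickly pear and 80.6% ± 2.57 on saguaro (SD, n = 6). The share was lower on prickly pear than on lab food in all 6 strains (exact permutation p = 0.0313, two-sided, the smallest 6 strains can give, and 0.0563 after adjustment over 9 tests). The median SD of log2 CPM between strains was 0.47 in the Santa Catalina saguaro group and 0.24 to 0.32 in the other groups (n = 3 each).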
